A study of Homo sapiens with 6 samples.

How the data were processed

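Gene expression was measured by RNA sequencing in human pulmonary microvascular endothelial cells, primary cells that line the small vessels of the lung. Per the labels' protocols, a commercial culture at 80 to 90% confluence was serum-starved overnight and transfected with a synthetic miR-887-3p mimic or with a commercial negative control duplex. RNA was taken 48 h later, and libraries were made with a SMART-Seq kit from small amounts of total RNA. The 6 samples form 2 groups of 3, named Control and miR-887-3p here after the labels. No untransfected sample was analysed here, and small RNA libraries that the protocol also names were not analysed here. Nothing in the labels says whether the samples of a group are separate cultures, so p-values measure only the spread between these samples, which may be technical.

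The authors deposited a table with a raw read count per gene and sample. Its column names use the abbreviation HMVEC, which does not name the lung, so the pulmonary origin rests on the sample labels alone. The submitters' processing notes name HTSeq, DESeq2 and the genome build hg19; the aligner, the gene annotation, the versions and the strand setting are not given in the sources used here, so counts of genes that overlap another gene are uncertain. The deposited table also holds the authors' log2 fold change for each gene, per the file headers. It holds an adjusted p-value of the authors for each gene as well, per the file headers. These last columns were used only for a comparison of calls, and the counts were used for everything else. The table has 25375 rows. 6 symbols were listed on more than 1 row, with identical counts, and were kept once. XIST, TSIX and genes of the Y chromosome were left out, which left 25262 symbols. Of these, 23623 were matched by symbol, gene number or older symbol to GENCODE v29 on GRCh38, which served for positions, transcript length, GC content and 3' UTR sequence. Transcript length and GC content were those of a gene's longest annotated transcript of any type. The counts were made on another build, so all positions given are those of GRCh38.

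Total counts per sample lay between 24066996 and 29490736, and between 17177 and 17794 genes had a count. Pairs of samples within a group differed by 2.01 to 4.21 times the chi-square per gene that counting noise gives, over genes with at least 20 counts in the pair. Repeat libraries of one culture could differ as much, so this does not show separate cultures, and each sample was counted as a replicate because the labels number them so. A group with no count at all for a gene allows up to 3 counts, and a fold against such a group is a lower bound computed from that floor over the whole group and from total counts. Floors and counting intervals cover counting error only, since reads amplified by PCR are not independent molecules.

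Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10), the quasi-likelihood test on group alone and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. 13989 genes were tested. Standard errors are on the log2 scale and were derived from the test's F statistic. Levels are CPM, the values of the cpm function of edgeR with TMM scaling. Fixed gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists with at least 5 tested members. camera with an estimated correlation and fry were alternatives. 29 lists were fixed, 28 of which could be tested. Cytokine and adhesion lists were written with knowledge that published work on this microRNA in endothelium dealt with such genes, so they are not independent evidence of direction, and neither are the preset genes among them.

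For the seed test, tested protein-coding genes were searched for the complement of miR-887-3p positions 2 to 8 in their longest annotated 3' UTR. 12570 tested genes had such a 3' UTR. The difference in median log2 fold change between genes with a 7mer-m8 or 8mer match and genes with no 6mer match was tested with a two-sided permutation test over genes (100000 resamples), with a bootstrap 95% interval (2000 resamples). Genes are not independent replicates, so this test describes these genes. The seed 7-mer was also ranked among the 7-mers that hold a CpG and occur in at least 50% as many UTRs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

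Before the data were examined, the design, the lists, the alternatives and the rule for named genes were fixed. The rule named the 12 largest rises and the 12 largest falls among called genes with a mean of at least 50 normalized counts in the higher group and no overlap between groups; up to 4 members of each list with the lowest p; 17 preset genes (CXCL10, CCL5, CX3CL1, VCAM1, ICAM1, SELE, CSF2, IL6, CXCL8, CCL2, PECAM1, CDH5, VWF, NOS3, KDR, ANGPT2 and FBXL7, which hosts MIR887); and up to 6 called genes with the largest falls among those with a seed site. Clone-named transcripts, pseudogenes, open-reading-frame names and antisense or LINC names without a known function were left out of the largest changes. That left out 1 gene among the rises and 1 among the falls. Genes named outside the rule are said to be so.

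The alternatives were other scalings, DESeq2 1.42.0, limma-voom, a robust variance model, no filter and a stricter filter (at least 50 counts in at least 3 samples), removal of GC content and transcript length trends per sample, a fold threshold, the replicate number as a block, and leaving out each sample in turn. DESeq2 gave no adjusted p for 1879 genes, which were left without one. The test was tried on simulated counts with the samples' means and library sizes (13817 genes run): it recovered 43 of 50 genes changed 1.25-fold, 45 of 50 changed 1.5-fold, 50 of 50 changed 2-fold and 50 of 50 changed 4-fold, and called 8 of 13617 unchanged genes. In a simulation with 1 shifted list, that list and none of the 28 unchanged lists passed. Genes were drawn independently in these count simulations, whereas the estimated correlation of the interferon response list was 0.807. Far fewer genes were changed in them than were called in the data. The count simulations therefore do not give the error rates for these data. With fold changes shuffled over 11770 genes, the seed test called 3 of 100 simulations without a shift, 53 of 100 with a shift of -0.1 and 98 of 100 with a shift of -0.2.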

Results

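The expression of genes was compared between lung microvascular endothelial cells that had received a synthetic mimic of the microRNA miR-887-3p and cells that had received a negative control duplex, 48 h after transfection, with 3 samples in each group. The question was how miR-887-3p changes gene expression in these cells. Total counts were 27119918, 24066996 and 29490736 in the Control samples and 27669324, 27442182 and 29134859 in the miR-887-3p samples. The 10 most abundant genes took 6.64 to 6.85% of counts in Control and 6.16 to 6.19% with the mimic.

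Cells with the mimic held far more transcripts of interferons, interferon-induced genes and chemokines, and of SELE, VCAM1 and ICAM1, than Control cells, and fewer transcripts of ribosomal proteins, keratins and many endothelial and matrix genes. CXCL10, a chemokine that attracts T cells, went from 0.161 ± 0.117 to 5636 ± 166 CPM (SD, n = 3 per group). Its counts were 8, 3 and 2 in Control and 152570, 158592 and 159758 with the mimic, a ratio of 34690 (95% exact binomial counting interval 20290 to 65150). Without Control replicate 1 that ratio was 59880 (25660 to 184400). IFNB1, which encodes interferon beta, had no count in the Control samples and 2002, 1943 and 2199 counts with the mimic, which is at least 1961-fold higher. Of 13989 tested genes, edgeR's quasi-likelihood test called 10942 (78.2%), 5459 higher and 5483 lower with the mimic. Many of these changes were small: 1438 of the called genes rose and 1308 fell by at least 2-fold, while 370 rose and 55 fell by at least 8-fold. How the calls split into higher and lower depended on the processing. Upper quartile scaling gave 5002 higher and 5898 lower, and removal of GC and length trends gave 5660 higher and 5103 lower. The groups did not overlap for 79.3% of tested genes, where chance gives 10% for 3 against 3 samples. The replicates were close, with a common biological coefficient of variation of 3.31%, and 94.4% of the variance of the log2 values lay on the first principal component, which parts the groups. In the authors' deposited table, 10434 genes had an adjusted p under 0.05, 5213 higher and 5221 lower, and 10098 of them were also called here, each with the same sign.

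Of the 12 genes named for the largest fitted rises, 6 genes besides IFNB1 had no count in any Control sample, so their rank rests on fitted values and only lower bounds are given for them. CD38, which encodes an enzyme that consumes NAD, was at least 1000-fold higher with the mimic, and the chemokine CCL8 at least 913-fold higher. IFNL1, a type III interferon, was at least 314-fold higher, IRG1, which makes itaconate, at least 256-fold, the calcium channel gene CACNA1I at least 210-fold and the chemokine CCL3 at least 185-fold. The others of the 12 were CXCL10, CXCL11, OASL, RSAD2 and CX3CL1. The fold of CCL5 (848), which is not among the 12, was above most of these bounds. CXCL11, a ligand of the same receptor as CXCL10, rose from 0.235 ± 0.229 to 1807 ± 45.6 CPM (SD, n = 3). Its Control counts were 2, 12 and 4, and its log2 fold change was 12.96 (edgeR adjusted p = 1.81e-31), or 14.01 without Control replicate 2.

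All 43 tested members of the interferon response list rose, with a median log2 fold change of 4.75 and a lowest value of 1.74, and all 43 passed when adjusted over the list alone. The list lay above the other genes (camera adjusted p = 8.51e-106), but that call was lost with an estimated correlation (adjusted p = 0.0512). OASL rose from 0.576 ± 0.155 to 1067 ± 28.3 CPM (SD, n = 3). RSAD2, which encodes the antiviral enzyme viperin, rose by 10.45 on the log2 scale (SE 0.09). IFIT2 rose by 7.67 (SE 0.06) and CMPK2 by 8.86 (SE 0.08). IFIT genes resemble one another in sequence, as do HLA genes, so single values of IFIT2 and HLA-F are uncertain. All 19 members of the class I antigen presentation list rose as well (19 adjusted over the list alone, median 2.00; camera adjusted p = 2.24e-34, and adjusted p = 0.0441 with an estimated correlation). They included HLA-F (log2 fold change 5.41), the immunoproteasome subunit PSMB9 (4.13), the peptide transporter TAP1 (3.56) and NLRC5 (3.10), a transactivator of class I genes.

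Of 26 chemokines and cytokines, 24 rose, 1 fell and 1 did not pass (25 passing adjusted over the list alone, median 4.74; camera adjusted p = 2.79e-72, and adjusted p = 0.0340 with an estimated correlation). The list was written with prior knowledge of such genes in connection with this microRNA and is not independent evidence of its direction. CCL5 rose from 1.28 ± 0.321 to 1069 ± 53.5 CPM (SD, n = 3). CX3CL1, a membrane-bound chemokine, rose from 0.278 to 264 CPM, CCL20 from 2.13 to 705 CPM and IL6 from 18.3 to 1144 CPM. CSF2, which encodes a growth factor of granulocytes and macrophages, rose by 5.27 on the log2 scale (SE 0.07), CCL2 by 3.78 (SE 0.05) and CXCL8 by 2.54 (SE 0.04). The member that fell was IL33 (log2 fold change -1.70), which was named after its value was seen. Of 24 genes of the NF-kB response, 23 rose and 1 fell (24 adjusted over the list alone, median 2.14; camera adjusted p = 5.00e-40, and adjusted p = 0.0340 with an estimated correlation). TNFAIP3, an inhibitor of the pathway, rose by 4.27, PTX3 by 4.16, TNFAIP2 by 4.10 and SOD2 by 3.68. The member that fell, TRAF3, named after its value was seen, had a log2 fold change of -0.09. That call was lost with DESeq2 (adjusted p = 0.0702), with GC and length trends removed (log2 fold change 0.06, adjusted p = 0.112), with a stricter filter, with the replicate block, and without Control replicate 1 or 2 (adjusted p = 0.123 and 0.0607) or miR-887-3p replicate 1 or 3 (0.106 and 0.0841), over a range of 0.00150 to 0.123.

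**Figure D1:**
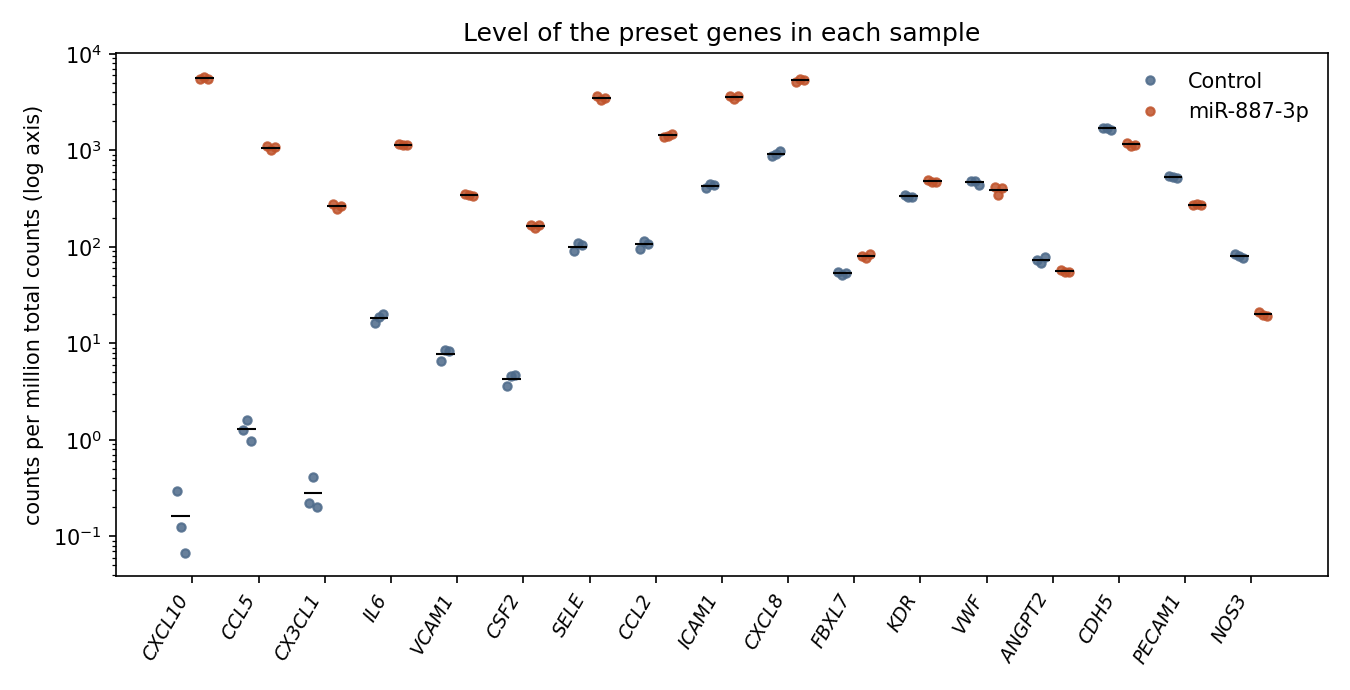
CPM, by total counts and without TMM scaling, of the 17 preset genes on a log axis; each point is a sample (3 Control, 3 miR-887-3p) and each bar the mean of a group. The chemokine and cytokine genes, VCAM1, ICAM1 and SELE sit higher in the miR-887-3p samples, with CXCL10 counts of 8, 3 and 2 in Control against 152570, 158592 and 159758, while NOS3, PECAM1 and CDH5 sit lower.

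Leukocyte adhesion genes moved both ways, with SELE, VCAM1 and ICAM1 up and PECAM1 down. SELE (E-selectin) rose from 100 ± 10.1 to 3494 ± 170 CPM, VCAM1 from 7.77 ± 1.05 to 346 ± 10.2 CPM and ICAM1 from 428 ± 22.8 to 3609 ± 138 CPM (SD, n = 3). CD47 rose by 2.66 on the log2 scale. Of 18 leukocyte adhesion genes, 9 rose and 8 fell (17 adjusted over the list alone, median 0.13; camera upward, adjusted p = 0.00176, and adjusted p = 0.196 with an estimated correlation). PECAM1, a junctional adhesion molecule, fell by 0.94 on the log2 scale (SE 0.04).

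Endothelial genes moved both ways, mostly down. Of 23 genes of endothelial identity, 17 fell and 6 rose (23 adjusted over the list alone, median -0.55; camera adjusted p = 0.000158, and adjusted p = 0.374 with an estimated correlation). EMCN, a sialoglycoprotein of venous and capillary endothelium, fell from 96.3 ± 2.85 to 7.90 ± 0.544 CPM, and NOS3, the endothelial nitric oxide synthase, from 79.6 ± 3.77 to 20.2 ± 1.10 CPM (SD, n = 3). MMRN2 fell by 1.53 and CLEC14A by 1.37 on the log2 scale. CDH5, the endothelial cadherin, fell by 0.53 (SE 0.04) and ANGPT2 by 0.37 (SE 0.05), whereas KDR, a receptor for VEGF, rose by 0.54 (SE 0.04). VWF fell by 0.24 (SE 0.05; edgeR adjusted p = 0.000289), a call that was lost after GC and length trends were removed (log2 fold change -0.05, adjusted p = 0.222) and with a robust variance model (adjusted p = 0.0539), with adjusted p between 7.68e-11 and 0.222 over its alternatives. Of 28 junction genes, 11 rose and 14 fell (25 adjusted over the list alone, median -0.16; camera adjusted p = 0.502). CLDN5 fell by 1.90 and GJA1 by 1.34, and PVRL2 and S1PR1 rose by 1.34 and 1.15. Of 25 Notch and sprouting genes, 8 rose and 15 fell (23 adjusted over the list alone, median -0.53; camera adjusted p = 0.473). NRARP fell by 2.03, and PDGFB, FLT1 and VEGFC rose by 1.53, 1.30 and 1.02. Of 24 genes of coagulation, fibrinolysis and vascular tone, 13 rose and 10 fell (23 adjusted over the list alone, median 0.55; camera adjusted p = 0.133). PTGS2, an enzyme of prostaglandin synthesis, rose by 4.88 on the log2 scale, TFPI2 from 11.5 to 64.9 CPM and EDN1 (endothelin) by 1.53 on the log2 scale, and F2R, a thrombin receptor, fell by 1.53.

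The 12 largest falls were TMEM35, TSPAN11, GJA5, DIO2, SLC44A5, SESN3, ERVFRD-1, ETV1, REEP2, PTPN22, LYVE1 and EMCN. GJA5, a connexin of arterial endothelium, fell from 8.07 ± 0.698 to 0.297 ± 0.103 CPM, and TMEM35 from 7.29 ± 0.602 to 0.193 ± 0.0956 CPM (SD, n = 3). TSPAN11 fell by 4.78 on the log2 scale (SE 0.13), DIO2, which activates thyroid hormone, by 4.73 (SE 0.23), and PTPN22 by 3.68 (SE 0.08).

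**Figure D2:**
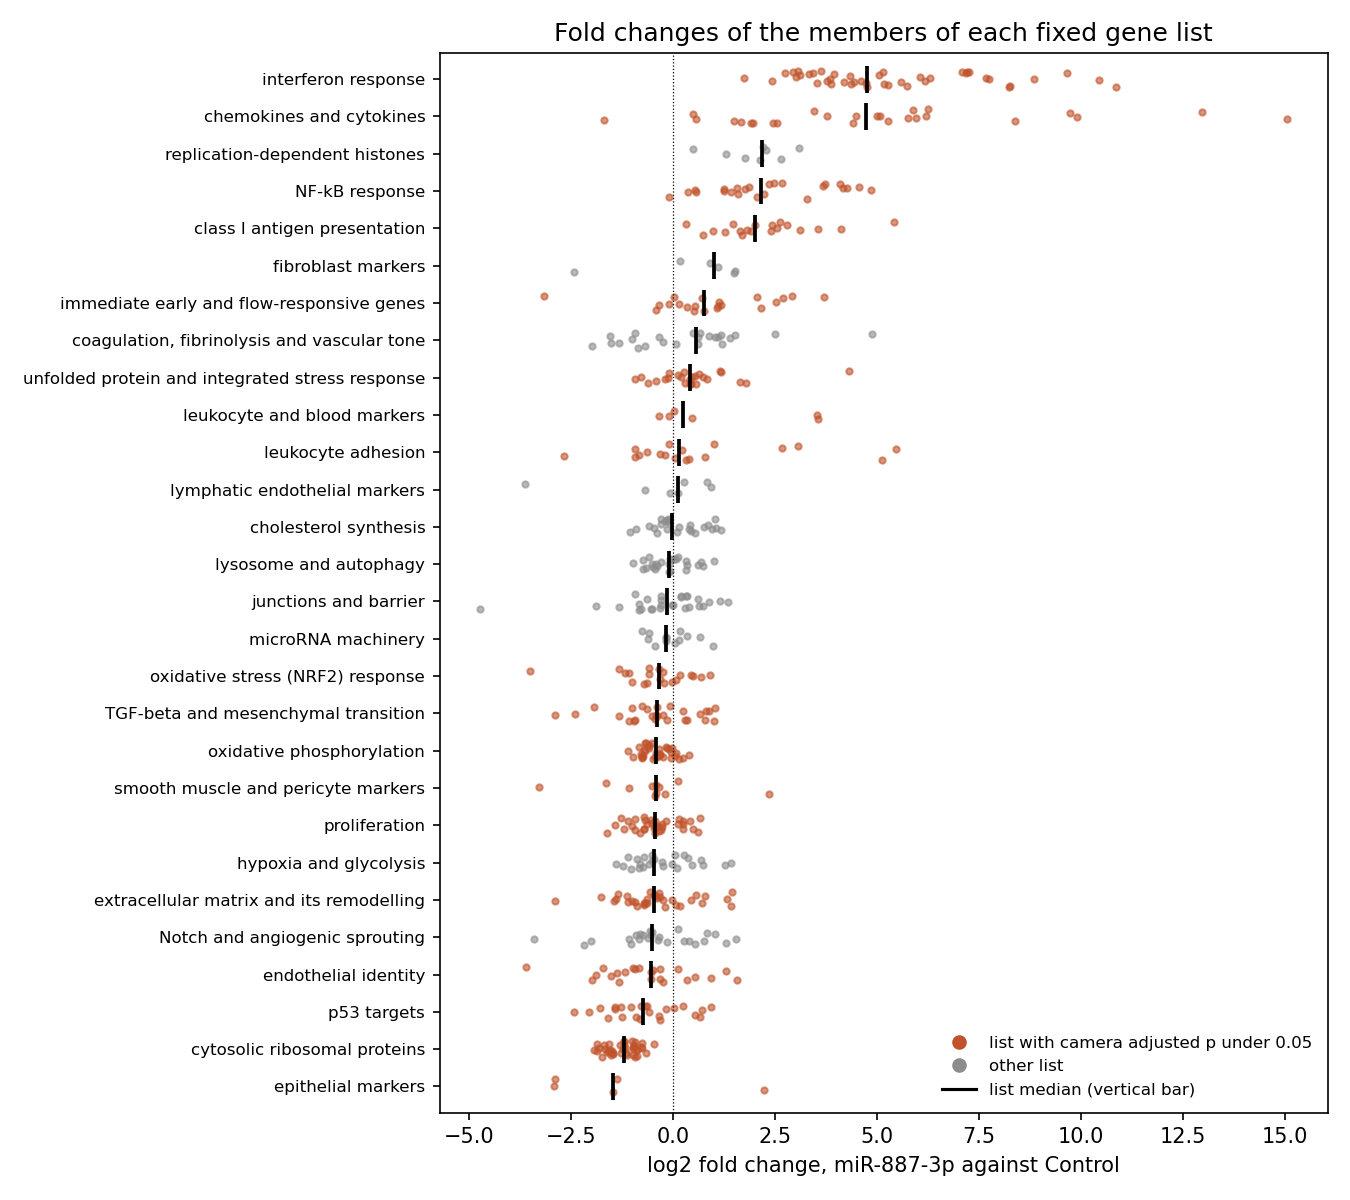
Log2 fold change (miR-887-3p against Control) of every tested member of each tested list; each point is a gene, the vertical bar is the list's median, and coloured points mark lists with a camera adjusted p under 0.05. All 43 interferon response genes lie above 0 and all 40 ribosomal protein genes lie below 0.

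All 40 cytosolic ribosomal protein genes fell (40 adjusted over the list alone), with a median log2 fold change of -1.20 and a range of -1.94 to -0.48. The list lay below the other genes (camera adjusted p = 8.97e-27), a call that was lost with an estimated correlation (adjusted p = 0.196). RPL3 fell from 2892 ± 63.4 to 825 ± 11.2 CPM and RPLP0 from 2636 ± 58.5 to 727 ± 2.69 CPM (SD, n = 3). RPL13A fell by 1.94 and RPS3A by 1.87 on the log2 scale. Ribosomal protein genes have many pseudogenes, so part of their reads may have been lost or split in counting. All 40 fell under each of 4 scalings. These scalings moved the median log2 fold change of all tested genes only between -0.0492 and 0.00632, so falls of this size were bound to stay. Of 36 oxidative phosphorylation genes, 28 fell and 3 rose (31 adjusted over the list alone, median -0.42; camera adjusted p = 0.000972, and adjusted p = 0.309 with an estimated correlation). UQCRB fell by 1.12, ATP5O by 0.80, SDHC by 0.77 and ATP5A1 by 0.70. The 3 that rose, named after their values were seen, were NDUFA9 (0.38), NDUFV2 (0.24) and NDUFA1 (0.13), of which NDUFA1 lost its call with upper quartile scaling (adjusted p = 0.101) and without Control replicate 1 (0.0821). Of 25 hypoxia and glycolysis genes, 7 rose and 15 fell (22 adjusted over the list alone, median -0.47; camera adjusted p = 0.0536). GAPDH, LDHA and BNIP3L fell by 1.10, 1.04 and 1.40, and HK2 rose by 1.41. That list passed without Control replicate 2 (camera adjusted p = 0.0445) or 3 (0.0336), with a range of 0.0249 to 0.327 over the camera alternatives.

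Fewer transcripts of cell division and p53 target genes were counted with the mimic. Of 36 proliferation genes, 27 fell and 9 rose (36 adjusted over the list alone, median -0.45; camera adjusted p = 0.00395, and adjusted p = 0.399 with an estimated correlation). KIF20A fell by 1.63, CDC20 by 1.42, PLK1 by 1.29 and TYMS by 0.93. Of 24 p53 targets, 18 fell and 5 rose (23 adjusted over the list alone, median -0.73; camera adjusted p = 5.42e-06, and adjusted p = 0.0512 with an estimated correlation). ZMAT3 fell by 2.44, FDXR by 2.07 and CCNG1 by 1.43 on the log2 scale, and TP53INP1 went from 177 to 50.6 CPM. The 5 that rose, named after their values were seen, were BBC3 (0.92), PLK3 (0.71), FAS (0.66), XPC (0.54) and AEN (0.25). Each of 8 tested histone genes that depend on replication rose (8 adjusted over the list alone, median 2.17), including HIST2H2BE, from 0.993 to 8.51 CPM, HIST1H2BC (2.65), HIST1H2AC (1.76) and HIST1H2BK (1.29). With DESeq2, HIST1H1C (0.50), named after its value was seen, lost its call (adjusted p = 0.0509). That list did not pass (camera adjusted p = 0.0867), and its genes share sequence with one another, so the single values are uncertain.

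Of 25 genes of the unfolded protein and integrated stress response, 18 rose and 6 fell (24 adjusted over the list alone, median 0.42; camera adjusted p = 0.00176, and adjusted p = 0.223 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 4.30, DNAJB9 by 1.78, XBP1 by 1.63 and PPP1R15A by 1.17. Of 21 immediate early and flow-responsive genes, 15 rose and 4 fell (19 adjusted over the list alone, median 0.75; camera adjusted p = 0.000158, and adjusted p = 0.196 with an estimated correlation). KLF4 rose by 3.71, DUSP5 by 2.15 and JUNB by 2.06, and DUSP4 fell by 3.16. SPRY2 (-0.41), SPRED1 (-0.36) and MYC (-0.11), named after their values were seen, also fell, and MYC lost its call with GC and length trends removed (adjusted p = 0.578). Of 20 NRF2 genes, 13 fell and 5 rose (18 adjusted over the list alone, median -0.34; camera adjusted p = 0.0432, and adjusted p = 0.196 with an estimated correlation). TKT and SLC7A11 fell by 1.33 and 1.02, while HMOX1 rose by 0.91. The others that rose, named after their values were seen, were ABCC2 (0.68), FTH1 (0.49), GCLM (0.44) and GCLC (0.17). The call on the NRF2 list was lost without miR-887-3p replicate 1, 2 or 3 (camera adjusted p = 0.0581, 0.0570 and 0.0543, with a range of 0.0125 to 0.327 over the camera alternatives).

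Matrix and mesenchymal genes were mostly lower. Of 34 matrix genes, 24 fell and 7 rose (31 adjusted over the list alone, median -0.48; camera adjusted p = 0.00221, and adjusted p = 0.475 with an estimated correlation). The crosslinking enzyme LOX fell by 1.76, the collagenase MMP1 by 1.46, LAMA4 by 1.39 and MMP2 by 1.35. Of 27 TGF-beta and mesenchymal genes, 16 fell and 9 rose (25 adjusted over the list alone, median -0.40; camera adjusted p = 0.0192, and adjusted p = 0.399 with an estimated correlation). VIM, which encodes vimentin, fell from 6871 ± 218 to 1780 ± 63.1 CPM (SD, n = 3), PMEPA1 fell by 2.91 on the log2 scale, LTBP2 by 2.40 and TGFBI by 1.32. Of 24 cholesterol synthesis genes, 11 rose and 11 fell (22 adjusted over the list alone, median -0.02 and mean 0.13; camera adjusted p = 0.402). STARD4, SQLE and LSS rose by 1.18, 1.04 and 0.96. Of 25 lysosome and autophagy genes, 8 rose and 15 fell (23 adjusted over the list alone, median -0.10; camera adjusted p = 0.473), with CTSL and GRN up by 0.99 and 0.72, and ASAH1 and PSAP down by 0.98 and 0.66. Of 13 genes of the microRNA machinery, 5 rose and 7 fell (12 adjusted over the list alone, median -0.17; camera adjusted p = 0.755). AGO3 and TNRC6B rose by 0.98 and 0.65, and AGO1 and PRKRA fell by 0.77 and 0.62. XPO5 (0.34), DROSHA (0.17) and DGCR8 (0.14), named after their values were seen, also rose, and DGCR8 lost its call with upper quartile scaling (adjusted p = 0.0807) and without miR-887-3p replicate 1 (0.0554). None of the 13 listed mitochondrially encoded transcripts could be tested.

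Markers of other cell types moved in different directions. Of 5 tested epithelial markers, KRT7, KRT19, KRT18 and KRT8 fell, by 2.93, 2.91, 1.48 and 1.37 on the log2 scale, and MUC1, named after its value was seen, rose by 2.24 (5 adjusted over the list alone, median -1.48; camera adjusted p = 6.99e-07, and adjusted p = 0.0441 with an estimated correlation). These keratins are also made by some endothelial cells, and EPCAM and CDH1, markers of epithelium named outside the rule after their values were seen, had 4 and 7 counts over the Control samples. Of 11 smooth muscle and pericyte markers, 7 fell and 1 rose (8 adjusted over the list alone, median -0.43; camera adjusted p = 0.0227, and adjusted p = 0.196 with an estimated correlation). RGS5 fell from 1322 ± 46.8 to 135 ± 2.61 CPM (SD, n = 3), NOTCH3 by 1.65, ACTA2 by 1.07 and SMTN by 0.44 on the log2 scale. The member that rose, PDGFRB, named after its value was seen, had 11 counts over the Control samples and 59 with the mimic, with a log2 fold change of 2.34, or 2.95 without Control replicate 2. Of 6 fibroblast markers, COL1A1, COL1A2, COL3A1 and PDGFRA rose, by 1.52, 1.48, 1.09 and 0.89, and POSTN fell by 2.43, PDGFRA being named after its value was seen (5 adjusted over the list alone). The call of PDGFRA was lost with DESeq2 (adjusted p = 0.118), without Control replicate 1 (0.0990) and without miR-887-3p replicate 3 (0.0923). The median (0.99) and mean (0.45) of that list were above 0, while camera pointed down without passing (adjusted p = 0.473). Of 7 lymphatic markers, MMRN1 and PROX1 rose by 0.92 and 0.84, and LYVE1 and TFPI fell by 3.63 and 0.69 (4 adjusted over the list alone, median 0.11, mean -0.32; camera adjusted p = 0.834). Of 6 tested leukocyte and blood markers, CD68 rose by 3.54 and LST1 by 3.56, and FCER1G (0.47), LYZ (0.01), LCP1 (-0.10) and CORO1A (-0.35) did not pass (2 adjusted over the list alone, median 0.24). LYZ and LCP1 were named after their values were seen, and the log2 fold change of LST1 was 4.58 without Control replicate 3. That list passed narrowly (camera adjusted p = 0.0474, and adjusted p = 0.196 with an estimated correlation), and the call was lost without Control replicate 1, 2 or 3 (adjusted p = 0.0716, 0.0816 and 0.0694, with a range of 0.0438 to 0.327 over the camera alternatives). PTPRC, the general leukocyte marker, named outside the rule after its value was seen, had 2 counts over the Control samples and 5 with the mimic.

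The hairpin of miR-887 lies on chromosome 5 at 15935182 to 15935260 of GRCh38 on the plus strand, and the sequence of miR-887-3p (GTGAACGGGCGCCATCCCGAGG in DNA letters) at 15935229 to 15935250. It falls in an intron of FBXL7 (15500196 to 15939795) in each of the 3 annotated transcripts that span it. FBXL7 rose from 52.8 ± 1.52 to 81.4 ± 3.28 CPM (SD, n = 3; log2 fold change 0.62, SE 0.04, edgeR adjusted p = 1.06e-12). The mature microRNA itself is not measured by these libraries.

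**Figure D3:**
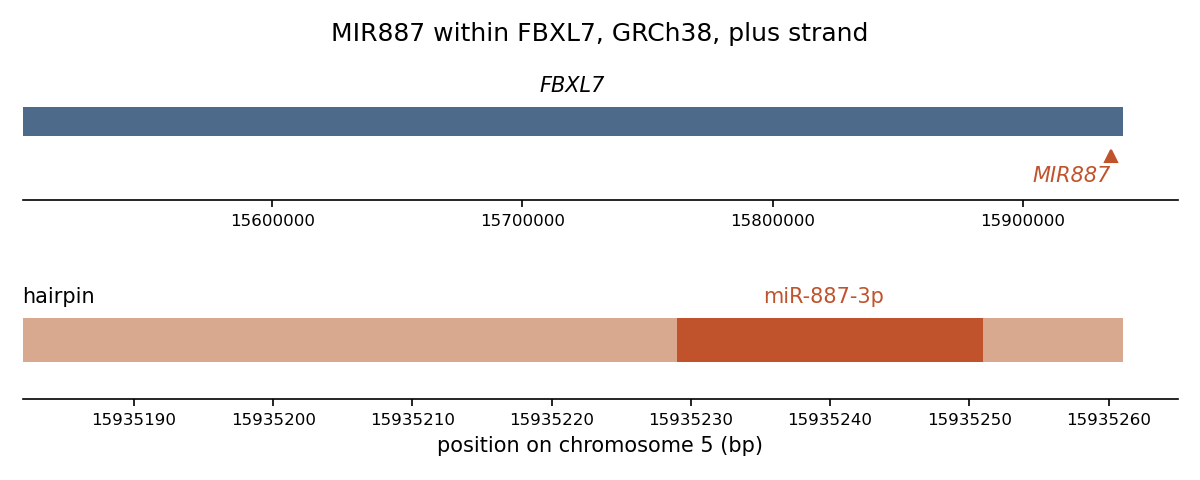
Position on chromosome 5 (bp, GRCh38) of FBXL7 from 15500196 to 15939795 with the place of MIR887 (upper panel), and of the hairpin from 15935182 to 15935260 with miR-887-3p from 15935229 to 15935250 (lower panel). The hairpin lies near the 3' end of FBXL7, on the same strand.

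Transcripts with a seed match in the 3' UTR were slightly lower as a group. The 257 tested genes with the 7mer-m8 site CCGTTCA had a median log2 fold change of -0.13, and the 11513 genes with no 6mer match had a median of 0.00, a difference of -0.127 (95% bootstrap interval -0.188 to -0.0373; two-sided permutation p = 0.0107). 125 of the 257 genes with a site fell and 82 rose, and 48.6% fell against 40.4% of genes without a match. The shift did not pass for the 45 genes with an 8mer site (difference -0.0588, permutation p = 0.609) or for the 1057 genes with a 6mer match or better (difference -0.0424, permutation p = 0.0770). Among 4729 7-mers with a CpG in 3' UTRs, 425 (8.99%), the seed among them, had a difference as low or lower.

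The largest falls among called genes with a site were those of VCAN, SNCAIP, GRIK4, MAPT, DACT3 and NOS3, each with a 7mer-m8 site in its longest annotated 3' UTR. That UTR can belong to a minor transcript, and counts are per gene, so the main mRNA may lack the site. Which transcripts were present was not checked, so NOS3, SNCAIP and the others are not shown to be targets. VCAN, which encodes the matrix proteoglycan versican, fell by 2.91 on the log2 scale (SE 0.11), and its site lies on chromosome 5 at 83580546 to 83580552 (plus strand) within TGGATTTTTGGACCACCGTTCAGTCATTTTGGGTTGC. The site of NOS3 lies on chromosome 7 at 151003824 to 151003830 (plus strand) within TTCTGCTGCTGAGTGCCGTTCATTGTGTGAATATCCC, in the 3' UTR of the transcript ENST00000484524.5. SNCAIP fell by 2.70 on the log2 scale (SE 0.27), GRIK4 by 2.63 (SE 0.50, log2 fold change -3.52 without miR-887-3p replicate 3), MAPT by 2.35 (SE 0.39) and DACT3 by 2.02 (SE 0.31). The sites of SNCAIP, GRIK4 and MAPT lie on chromosome 5 at 122440711 to 122440717, chromosome 11 at 120987273 to 120987279 and chromosome 17 at 46026291 to 46026297, all on the plus strand, and that of DACT3 on chromosome 19 at 46650542 to 46650548 on the minus strand. Of these, GRIK4, MAPT, DACT3 and SNCAIP were near the lower end of the tested levels, at 0.469 to 1.72 CPM in Control.

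**Figure D4:**
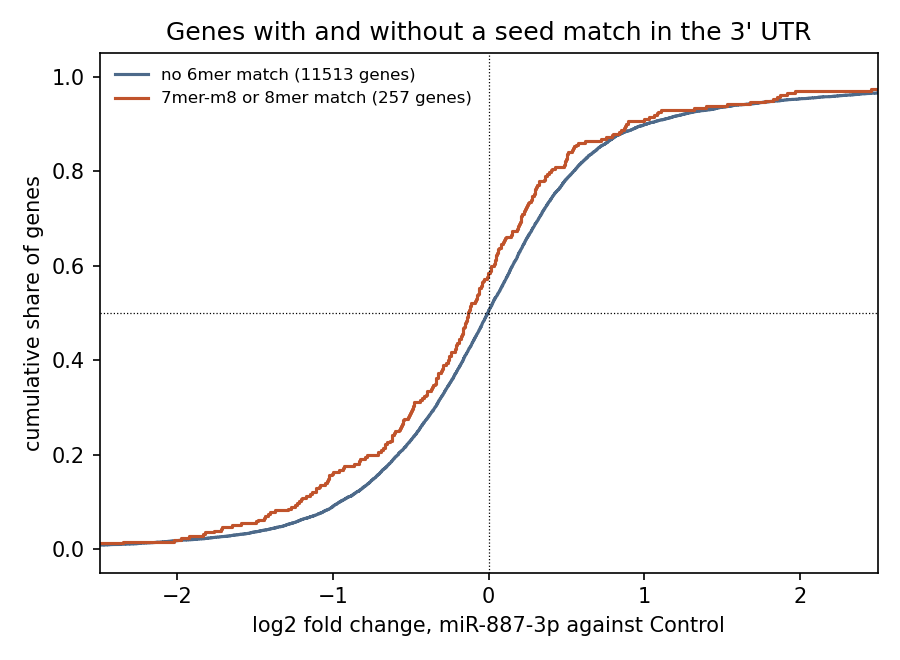
Cumulative share of tested genes against log2 fold change (miR-887-3p against Control) for 257 genes with a 7mer-m8 or 8mer match and 11513 genes with no 6mer match in the 3' UTR. The curve of genes with a match lies to the left, with medians differing by -0.127.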

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

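Upper quartile and total count scaling, the seed test on DESeq2 or trend-corrected fold changes, and the blocked list test with an estimated correlation were chosen after seeing the data. The count of called genes stayed between 9977 and 11482 under the other tools, scalings, filters and corrections, against 10942, and between 10580 and 10773 when 1 sample was left out. It was 2746 with a log2 fold change of at least 1 required, by construction of that threshold. DESeq2 called 10323 genes, 10028 of them shared. Of 145 named genes, 144 kept their direction and side of the threshold under every alternative that gave a value; the exception was VWF (adjusted p between 7.68e-11 and 0.222), for which the cause was not tested. Samples were not paired by number, as the deviations of same-numbered samples correlated at 0.0258, -0.0516 and -0.0544. With the replicate block 10835 genes were called, 16 lists passed, and the seed difference was -0.126. Of 28 lists, 18 passed with the preset correlation and 17 or 18 without any 1 sample. With an estimated correlation 4 passed, and 0 with an estimated correlation and the replicate block. An estimated correlation leaves little power with 6 samples, so a loss under it does not show that a list did not move. All 43 interferon response genes rose and all 40 ribosomal protein genes fell. The cause of the losses was not tested. fry, which asks only whether a list moves one way, passed 26. The hypoxia and glycolysis list passed without Control replicate 2 (adjusted p = 0.0445), without Control replicate 3 (0.0336) and with no filter (0.0249). The NRF2 list was lost with the replicate block (0.0548), and the leukocyte list with it (0.0592) and with no filter (0.0949). Over the camera alternatives the adjusted p lay between 0.0125 and 0.327 for the NRF2 list, 0.0249 and 0.327 for the hypoxia list, and 0.0438 and 0.327 for the leukocyte list; fry, which does not compare a list with other genes, gave 6.99e-06, 3.75e-06 and 3.75e-06. The seed difference was -0.0588 with 8mer sites only and -0.0424 with 6mer sites, neither past the threshold; the first rests on 45 genes, and for the second the cause was not tested. Elsewhere it lay between -0.136 and -0.0989. The pseudocount alternative applied to normalized values only and was not run.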

Other observations

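The gene lists in the first paragraphs here were chosen after values had been seen, and so were the tests of leukocyte RNA, of another duplex and of the oligopyrimidine motif, and the count of sample splits. The 7-mer rank and the matched 3' UTR comparison were planned, but what they were held to was written after their results were seen, and the match in the rest of the transcript was added then. The tests on seed sites in inhibitors and on matched genes for ribosomal proteins were set before their results were seen. Adjusted p-values are from edgeR for genes and from camera, over 10 added lists, for lists.

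Lists of innate immunity overlap in part with genes already described: IFNB1, IFNL1, DDX58, IFIH1, USP18, TNFAIP3, TNIP1, NFKBIA, NFKBIE, CYLD and DUSP1 are in the report's lists or largest rises, and ADAR and DHX58 are in both the sensor and the inhibitor list. Of 12 tested complement genes, 10 rose, among them CFB from 0.929 to 744 CPM, C1S from 1.19 to 241 CPM and C3 from 13.9 to 345 CPM, while CD46 and CD59, which protect cells from complement, fell by 0.44 and 0.53 on the log2 scale (camera adjusted p = 4.10e-18, and adjusted p = 0.0195 with an estimated correlation). All 5 guanylate-binding proteins rose, with GBP5 from 0.445 to 92.4 CPM (camera adjusted p = 2.21e-22, and adjusted p = 0.0195 with an estimated correlation). Of 11 ligands of the TNF superfamily, 8 rose, TNFSF13B from 0.281 to 135 CPM, TNFSF10 from 23.9 to 514 CPM and TNF from 4.80 to 116 CPM, while TNFSF4 and TNFSF12 fell by 2.25 and 1.17 (camera adjusted p = 1.53e-06, and adjusted p = 0.0392 with an estimated correlation). Of 13 sensors of double-stranded RNA and their adaptors, 11 rose, including TLR3 (log2 fold change 5.19), IFIH1 (5.14) and DDX58 (4.75), and MAVS fell by 0.51 (camera adjusted p = 1.20e-14, and adjusted p = 0.0195 with an estimated correlation). Of 8 interferon and receptor genes, 6 rose and IFNAR1 fell by 0.20, where IFNLR1 lost its rise with DESeq2 (adjusted p = 0.0857) and without Control replicate 2 (0.0543) or miR-887-3p replicate 3 (0.0503), and IFNAR2 fell past the threshold with upper quartile scaling (0.0462) (camera adjusted p = 0.00149, and adjusted p = 0.0392 with an estimated correlation). Of 36 inhibitors of innate signalling, 27 rose, and SIGIRR, PTPN11, IRF2BP2 and TRIM27 fell (median 0.44; camera adjusted p = 5.40e-11, and adjusted p = 0.0195 with an estimated correlation).

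All 20 other transcripts that start with a terminal oligopyrimidine motif, a pyrimidine run at the 5' end shared by ribosomal protein mRNAs, fell (median -1.16; camera adjusted p = 2.39e-16, and adjusted p = 0.0392 with an estimated correlation). EIF4B fell by 1.93, EIF3L by 1.82, EEF1G by 1.65, EEF2 by 1.60 and EEF1A1 by 1.55; the last pair had been seen before the list was written. Of 12 small nucleolar RNA host genes, 9 fell, DANCR by 2.88, SNHG5 by 1.55 and GAS5 by 1.34, and SNHG15 and SNHG1 rose by 0.58 and 0.36 (camera adjusted p = 0.00281, and adjusted p = 0.292 with an estimated correlation). Of 21 other initiation factors, 6 rose and 9 fell (median -0.03; camera adjusted p = 0.371), and of 40 mitochondrial ribosomal proteins, 7 rose and 24 fell (median -0.19; camera adjusted p = 0.218).

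The real split called 10942 genes and the highest of the other splits called 0, with 1 of the 10 splits as large; 3 samples against 3 give too few splits for a share under 0.05.

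The rise of interferon and cytokine genes is set against 3 explanations. RNA from leukocytes stays undecided by its test, which needed none or nearly all of 14 leukocyte markers, haemoglobin genes left out, to rise. That rule was written after the values of these markers were seen, so its outcome carries no weight, and the values themselves follow. Of these, 2 rose (CD68 and LST1), and FCER1G, LYZ, LCP1 and CORO1A did not pass. The 8 under the filter, PTPRC among them, had 57 counts over the miR-887-3p samples and 39 over the Control samples. PTPRC had 5 and 2, against 470920 counts of CXCL10 with the mimic. The listed markers thus showed no broad rise of leukocyte transcripts. The Control samples also received a duplex, and all 43 interferon list genes rose against them (median log2 fold change 4.75). That argues against a response that every transfected duplex gives alike at 48 h. A response to this duplex or its preparation, whatever its seed, stays open, because the mimic was compared with a single other duplex. The rise of the sensors does not decide it, as they are interferon-induced themselves. A fall of inhibitors through seed sites also stays open: 3 of 36 listed inhibitors hold a site, of which TRIM27 fell (log2 fold change -0.13, a call lost with GC and length trends removed, adjusted p = 0.109) while PIAS1 (0.72) and ITCH (0.23) rose, and repression of translation without loss of mRNA would not be seen. An effect of miR-887-3p itself through other targets is not excluded.

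The fall of ribosomal protein transcripts is relative to other genes, as a scaling factor moves every gene of a sample alike and absolute amounts were not measured. Genes matched on GC content, transcript length and control level also had a negative median log2 fold change (-0.37 over 289 genes, SD 0.88). The list's median lay 0.82 below that of the matched genes (difference -0.825), with 40 of 40 members under the matched median. The match is incomplete for abundance (median 538 against 1013 CPM). Length and GC content were taken from each gene's longest annotated transcript (median 1916 bases for the list), which may not be its main mRNA. Whether the expressed mRNAs match in length and GC content was therefore not tested. A candidate explanation is a fall shared by transcripts with the oligopyrimidine motif: without EEF1A1 and EEF2, 18 of 18 others fell, with a median 0.819 below matched genes (difference -0.819). A response to transfection alike in both groups would not part them, since the Control samples also received a duplex. Whether the shared fall follows from interferon, from the mimic or from its preparation was not tested. The estimated correlation among ribosomal protein genes was 0.611, and with it the list did not pass (camera adjusted p = 0.196). That leaves open that these genes count as few independent observations.

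The lower median of genes with a seed site may follow the base composition of their 3' UTRs: 8.99% of the 7-mers with a CpG had a difference as low or lower, and the median over those 7-mers was itself -0.0528. Against site-free genes matched on 3' UTR length, 3' UTR GC content and expression the difference was -0.110 (95% bootstrap interval -0.179 to -0.00210). That interval treats genes as independent and ends close to no difference, and the closeness of the match was not measured. It therefore cannot settle whether these properties account for the lower median. A match in the rest of the transcript and none in the 3' UTR went with a difference of -0.0166 (permutation p = 0.650, 409 genes). A direct effect of the mimic on transcripts with a site is a hypothesis that these values leave open.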
